A study of Mus musculus with 23 samples.

How the data were processed

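The 23 libraries were assigned to 11 groups from their titles and characteristics. Titles and file headers of the Smad4 libraries give one genotype and the strain labels the opposite one, and the titles were followed. The choice of groups, the 9 comparisons, the main test, the named-gene rule and most alternatives were written down before the data were examined. The sequence reads were not used here, and no reads were aligned or counted again.

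According to the submitters' processing notes, reads were aligned to mm10 with Bowtie2 and peaks were found with HOMER, with versions not given in the sources used here. The signal values are normalised tag counts, which per the file headers HOMER findPeaks computed in each peak and scaled to 10 M tags per library. The score values are findPeaks scores, which per the file headers were computed by the same program for each deposited peak, and they were read and compared but entered no test. Per the file headers the peaks were found in each library by itself, in factor style, with a size and minimum distance of 200 bp, a false discovery rate of 0.001, a signal 4 times that of the surrounding 10 kb, a local Poisson p of 0.0001 and no input library. The tag threshold that this rate gave was 8 to 11 tags.

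Peaks on 19 autosomes and the X chromosome were kept, and 1205 of 1605886 peaks on other sequences were left out. Peaks that overlapped by at least 1 bp in any libraries were merged into 155137 regions with a median width of 261 bp and a maximum of 1437 bp, of which 26618 were called in all libraries and 25972 in 1. Where a library had several peaks in a region, the strongest gave its value. A region was assigned to the nearest protein-coding gene body within 50 kb, since the gene table (GRCm38.p6, 21631 protein-coding genes) gives no strand. The written plan had named the start of transcription instead. This placed 88.7% of regions, 56.6% inside a gene. The build was checked by peaks at gene ends, which overlapped 23.4% of ends, against 3.19% and 3.26% after shifts.

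A region was group-only when it was called in every library of one group and in none of the other. Such regions need not be closed in the other group. Of the 50 strongest per group, 34 in TIM4+ knockouts and 30 in controls had a peak of the other group within 1 kb. It was 31 and 17 for TIM4- knockouts and controls, 28 and 33 for TIM4- and TIM4+ knockouts. Libraries titled Smad4 knockout and control gave 31 and 38. For 48 h and 24 h it was 30 and 32, for 24 h and blood 27 and 23. Kupffer cells against 48 h gave 4 and 12, against blood 4 and 10. Over all group-only regions, not only the strongest, the share ran from 14.5% (48 h against Kupffer cells) to 39.9% (TIM4+ against TIM4- knockouts). Signal was tested in regions called in every library of both groups, as log2 of the normalised tag count plus 1, centred on the median of each library, with limma (moderated t with a mean-variance trend, two-sided, Benjamini-Hochberg, adjusted p of 0.05). Fold changes are therefore relative to the median region. Each comparison was repeated for the splits that mix its groups, of which the highest gave 31 calls. In such splits the real difference widens the residual spread, so they give no rate of false calls. In simulated data with planted changes of 4-fold size, limma recovered 97% to 99%, and of 2-fold size 34% to 67%. False calls made 1.29% to 8.55% of its calls there, above 5% for Kupffer cells against blood (8.55%), Smad4 (7.64%) and TIM4- against TIM4+ (5.88%). These rates were computed with the same numbers of libraries as in the comparisons, but with 200 planted changes and the same dispersion for all regions of a comparison. Real regions differ in spread, so the rates do not carry over to the real calls.

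Gene lists were written from general knowledge before the data were examined, 21 in all, and those reported are Kupffer identity, monocyte, LXR target, Notch target, TGF-β and BMP target, inflammatory, iron and heme, phagocytosis and complement genes, and markers of hepatocytes, liver endothelial, stellate, B, T and NK, and dendritic cells and neutrophils. Of 373 entries 371 were found in the gene table, Mx1 and Mx2 not. The net number of group-only regions of a list was compared with 10000 random lists matched on regions per gene, and p-values were adjusted over the 21 lists of a comparison. The mean log2 fold change per gene was tested in the same way, a test chosen after the data were seen. Where TIM4- cells were compared, lists with Timd4 were also tested without it, which was likewise added after the data were seen. The smallest p such a test can give is 0.0001. Kupffer-gained regions and the monocyte set were compared with changed regions by Fisher exact tests (two-sided) over all regions of a comparison. Numbers given as by chance are those expected from the sizes of the set and of the changed regions. The monocyte set lacks peaks in Kupffer cells by definition. Its excess among regions absent from a Kupffer group, or lower in one, is therefore partly built in, and does not show that monocyte peaks returned. Kupffer-gained regions have peaks in every library of Kupffer cells from PBS mice by definition. Their excess among regions that fell against a Kupffer control is likewise partly built in. Overlaps with shared regions were added after the data were seen.

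Genes are named by a fixed rule. It takes 6 genes per direction with the strongest group-only region, up to 4 genes per list with the most group-only regions, and the 5 shared regions per direction with the largest fold change whose groups did not overlap. It also always takes Nr1h3, Smad4, Clec4f and Timd4, and for DLL4 Hes1, Hey1, Nrarp and Dtx1. Marco in Kupffer cells against 48 h, Pecam1, Tek, Emcn and Gata4 among endothelial markers, Vcan and Marco in TIM4- against TIM4+ cells, and Dlgap2 and Tenm2 among genes of Kupffer-gained regions lie outside the rule and were chosen after the values were seen. The text gives fewer genes than the rule allows.

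Alternatives were lists of equal length within a comparison, these with regions of the full lists of the other group removed, a tag threshold 2 times as strict, peaks widened by 100 bp or trimmed to their centre, no centring, quantile normalisation, all libraries of an experiment in the fit, the weakest regions left out, a pseudocount of 5, assignment within 10 and 100 kb, a replicate block and each library left out. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table (1.17.8).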

Results

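Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA and leaves sequencing adapters, in 23 mouse libraries that form 11 groups in 4 experiments. The repopulation experiment used mice whose Kupffer cells, the resident macrophages of the liver, carry the diphtheria toxin receptor and die after toxin. It held 2 libraries of blood Ly6C-high monocytes and 2 of Kupffer cells from mice given PBS. It also held 3 libraries of repopulating liver macrophages taken 24 h after toxin and 2 taken after 48 h. The Nr1h3 experiment concerned the nuclear receptor LXRα, which Nr1h3 encodes. It held 2 libraries each of TIM4+ Kupffer cells from floxed controls, TIM4+ cells from Clec4f-cre knockouts and TIM4- cells from the same knockouts. The Smad4 experiment held 2 libraries titled knockout and 2 titled control. Their strain labels give the opposite genotypes, so every Smad4 direction here follows the titles and would turn if the strain labels were right. The culture experiment held 2 libraries of untreated bone marrow-derived macrophages grown for 4 days and 2 of such cells given the Notch ligand DLL4 for 24 h.

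Library depth, in M tags, was 12.3 and 14.2 for blood monocytes, 10.7, 11.01 and 10.5 for repopulating macrophages at 24 h, 11.5 and 13.6 at 48 h, and 10.55 and 10.4 for Kupffer cells. The Nr1h3 controls held 17.3 and 15.1 M, the TIM4+ knockouts 15.7 and 14.7 M, and the TIM4- knockouts 17.0 and 18.4 M. The libraries titled Smad4 knockout held 17.9 and 16.1 M and those titled control 16.5 and 18.3 M. Untreated cultured macrophages held 16.3 and 11.4 M and DLL4-treated ones 13.8 and 14.6 M. The share of tags in called peaks ran from 15.4% to 54.7%, and the deposited lists held 48775 to 104206 peaks. That share was 29.7% ± 5.21 (SD, n = 2) in Nr1h3 controls, 24.25% ± 3.30 (n = 2) in TIM4+ knockouts and 42.5% ± 1.79 (n = 2) in TIM4- knockouts. It was 17.5% ± 2.96 (n = 2) in libraries titled Smad4 knockout and 22.4% ± 4.03 (n = 2) in those titled control. Replicates of a group shared 71.2% to 78.8% of their regions, with Pearson correlations of 0.928 to 0.970 over shared regions, which are not independent replicates. A region without a peak in a library has no deposited value, so signal was compared only in regions called in every library of both groups, here named shared regions. The p-values of limma set a change against a spread between libraries that is largely pooled over regions of like signal. With 2 or 3 libraries per group they say little of the spread at a single region. Very small ones also hang on the normalisation, such as that of Nr3c2 below, at 4.9e-59 and at 7.9e-17 after quantile normalisation (limma). P-values of list permutations compare a list with random gene lists, and those of Fisher tests count regions. Titles of the repopulation libraries carry mouse numbers, while other titles give only replicate or library numbers, and the labels do not say that each came from a separate animal. Signals are normalised tag counts scaled to one depth for all libraries, coordinates are mm10, and log2 fold changes come from limma after each library was centred on its median.

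The first comparison asked how far repopulating liver macrophages, 24 h after toxin, differed from blood monocytes. Whether they derive from such monocytes was not tested, so gains and losses are differences between the groups. Genes of Kupffer cell identity gained accessibility. Of the 75 shared regions of that list, 21 rose, 2 fell and 52 did not pass the test (21 and 2 adjusted over the list alone). Itga9, an integrin alpha subunit, had 12 regions called only in the repopulating cells, and 4 of its 8 shared regions rose, the strongest by 1.94 on the log2 scale (SE 0.14, limma adjusted p = 1.6e-10). Among LXR targets, which serve cholesterol efflux and lipid synthesis, 30 of 99 shared regions rose, 8 fell and 61 did not pass (34 and 8 adjusted over the list alone). Abca1, the cholesterol exporter, rose at 6 of its 10 shared regions, the strongest by 2.06 (SE 0.26, limma adjusted p = 1.0e-06). Regions of monocyte genes moved the other way, with 21 of 83 lower, 7 higher and 55 not passing (25 and 7 adjusted over the list alone). S100a4, which encodes a calcium-binding protein abundant in myeloid cells, fell by 1.70 (SE 0.25, limma adjusted p = 6.9e-06). The chemokine gene Cxcl2 rose at 2 of 3 shared regions, the strongest by 1.85 (SE 0.17, limma adjusted p = 4.5e-09).

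The region with the largest change at 24 h lay inside Abhd12, a lysophospholipid lipase gene (chromosome 2, 150840109 to 150840454). Its signal was 209 ± 69.5 (SD, n = 3) in repopulating macrophages and 9.88 ± 1.02 (n = 2) in monocytes, a log2 fold change of 4.48 (SE 0.26, limma adjusted p = 1.2e-12). Regions nearest Rgs1, Dmac1, Mtmr7 and Plekha1 followed with log2 fold changes of 3.73, 3.23, 3.22 and 3.22. The largest losses with a gene within 50 kb lay at Arhgef17 (-2.91, SE 0.29, limma adjusted p = 2.6e-08), Dzank1 (-2.83), Atp2b4 (-2.75) and Akna (-2.71). One of the pair of Nr1h3 regions rose by 1.13 (SE 0.23, limma adjusted p = 4.0e-04), and the single shared Clec4f region gave 0.10 (SE 0.35, adjusted p = 0.87). In all, 11783 of 45317 shared regions passed, 7555 higher and 4228 lower, relative to a median shift of -0.27. Without centring the split was 2077 higher and 5808 lower, and after quantile normalisation 5410 and 5155. Libraries are numbered here in the order of the series, and without blood library 1 the total was 6251, without blood library 2 it was 5386. Mean log2 fold changes per gene were set against matched gene lists, a test added after the data were seen. Permutation adjusted p-values were 0.020 for Kupffer identity, 0.0021 for monocyte genes, 0.017 for LXR targets and 0.041 for complement, where 11 of 39 shared regions rose, 3 fell and 25 did not pass (11 and 3 adjusted over the list alone). The dendritic cell markers also moved, with 9 of 32 shared regions lower, 1 higher and 22 not passing (9 and 1 adjusted over the list alone, permutation adjusted p = 0.041, and 0.072 after quantile normalisation).

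Peaks called in every library of one group and in none of the other numbered 2836 for repopulating macrophages at 24 h and 4221 for blood monocytes. Itga9 and Abca1, with 12 and 3 such regions in repopulating cells, headed their lists, and F13a1, the coagulation factor XIII A subunit gene of monocytes, had 3 in monocytes. The Kupffer identity list had 21 regions in repopulating cells alone and 4 in monocytes alone (permutation adjusted p = 0.0021), LXR targets had 15 and 4 (0.0147), and monocyte genes had 4 and 12 (0.58). Of the 21, 12 lay at Itga9, and the list was not tested without this gene. The sum of 7057 compares with 4121 in the highest of the other splits of these 5 libraries. Leaving out any 1 library loosens the criterion and gave 3635 to 5562 and 5505 to 9159 regions.

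**Figure D1:**
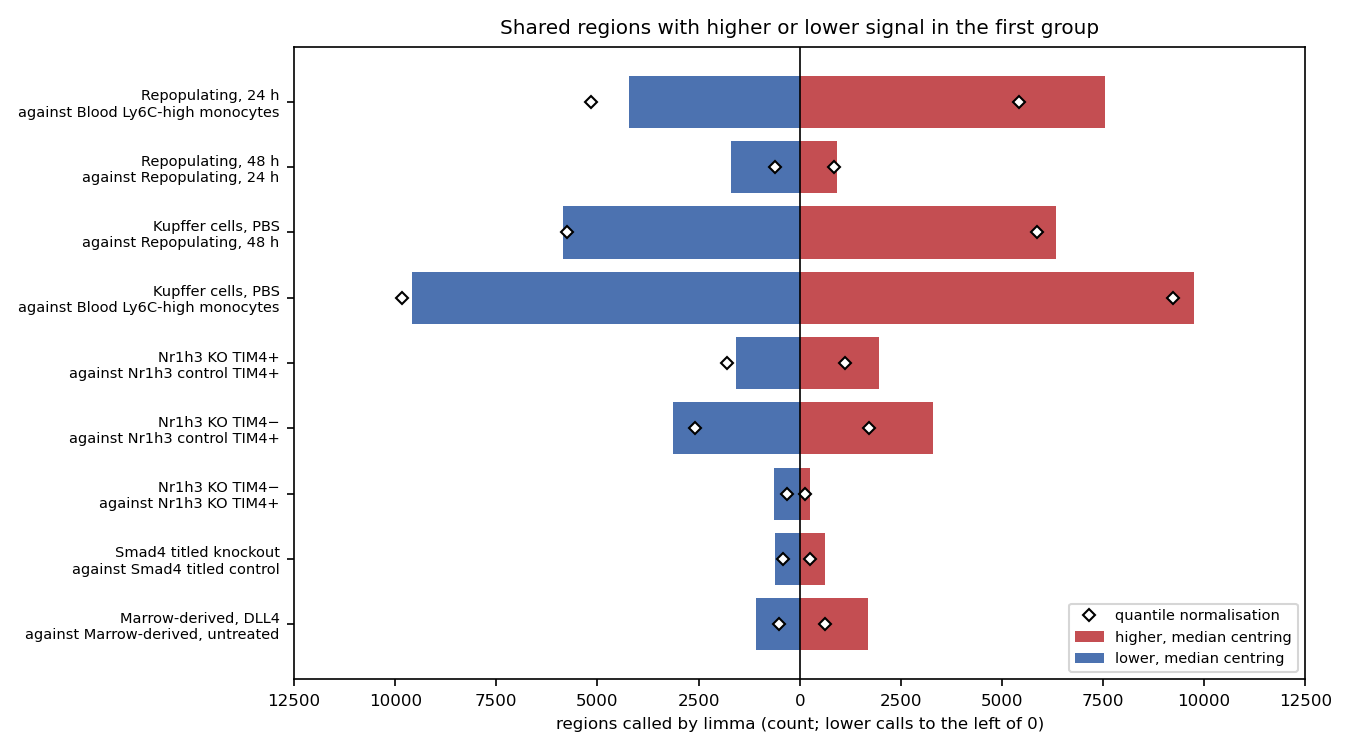
Number of shared regions past limma's adjusted p threshold in each comparison, higher (to the right) and lower (to the left) in the first-named group, as bars from 0, with diamonds for quantile normalisation. The comparison of Kupffer cells with blood monocytes gave the most calls (19319) and that of TIM4- with TIM4+ Nr1h3 knockout cells the fewest (881).

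The comparison of 48 h with 24 h asked what was added on the second day. Kupffer identity genes opened further. Of their 105 shared regions 13 rose, 2 fell and 90 did not pass (14 and 3 adjusted over the list alone). Pcolce2, a collagen-processing enhancer gene, rose by 2.85 (SE 0.28, limma adjusted p = 2.9e-06), from 30.3 ± 14.7 (SD, n = 3) to 229.7 ± 9.26 (n = 2) at chromosome 9, 95682667 to 95682931. Abca1 rose at 4 of 15 shared regions, the strongest by 1.21 (SE 0.24, limma adjusted p = 0.0040), within an LXR target list of which 9 of 115 rose, 1 fell and 105 did not pass (14 and 4 adjusted over the list alone). Paqr9, a membrane receptor family gene, and Cd5l, a secreted macrophage survival factor, had 6 and 4 regions called only at 48 h. The largest gains lay at Rcsd1 (3.16, SE 0.26, limma adjusted p = 1.9e-07), Ubxn2b (2.98) and Gtf2ird1 (2.87). The largest loss with a gene within 50 kb lay inside Runx1, a haematopoietic transcription factor gene (-2.03, SE 0.34, limma adjusted p = 0.0012). Of the pair of Nr1h3 regions, one rose by 0.80 (SE 0.22, limma adjusted p = 0.031), and the shared Clec4f region gave 0.48 (SE 0.33, adjusted p = 0.42).

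In this comparison 2637 of 48442 shared regions passed, 928 higher and 1709 lower, relative to a shift of 0.16. The split was 1104 and 253 without centring, 845 and 604 after quantile normalisation, and 414 and 392 with all libraries of the experiment in the fit. The total was 571 and 171 without 48 h libraries 1 and 2, and 1694, 1526 and 4992 without 24 h libraries 1, 2 and 3. Permutation adjusted p-values for mean fold changes were 0.0021 for Kupffer identity and 0.0084 for LXR targets and for complement, where 3 of 44 shared regions rose and 41 did not pass (3 higher adjusted over the list alone). For phagocytosis genes, of which 4 of 128 shared regions rose, 1 fell and 123 did not pass (1 higher adjusted over the list alone), the value was 0.035, and 0.056 after quantile normalisation. Peaks in one group alone numbered 5076 at 48 h and 607 at 24 h, and 2256 and 1702 with lists of equal length. Kupffer identity genes had 37 and 3 of them (permutation adjusted p = 0.0021). The sum of 5683 compares with 2638 in the highest of the other splits, and leaving out 1 library gave 6318 to 13871 and 1088 to 2358.

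Kupffer cells compared with repopulating macrophages at 48 h show what was still missing. Timd4, the gene of the phosphatidylserine receptor TIM4, had 14 regions called in every Kupffer library and in no repopulating library. Marco, a scavenger receptor gene chosen after the values were seen, had 2 such regions and was higher at 8 of 8 shared regions, the strongest by 1.95 (SE 0.34, limma adjusted p = 1.1e-05). Paqr9 was higher in Kupffer cells at 6 of 6 shared regions, the strongest by 2.26 (SE 0.34, limma adjusted p = 5.3e-07). Clec4f, the lectin gene whose promoter drives the Kupffer cell cre line, was higher at 2 of 3 shared regions, by 2.10 (SE 0.25, limma adjusted p = 1.9e-09) and 1.27 (SE 0.34, adjusted p = 0.0040). Slc7a11, the cystine transporter gene, was lower in Kupffer cells at 5 of 5 shared regions, the strongest at -2.95 (SE 0.30, limma adjusted p = 1.6e-11). The Notch target Nrarp was lower at both of its shared regions, the strongest at -2.18 (SE 0.33, limma adjusted p = 5.4e-07). The region inside Map3k4 (4.30, SE 0.27, limma adjusted p = 2.5e-19) was the largest gain with a gene within 50 kb. Itih5 (-3.63, SE 0.25, limma adjusted p = 4.2e-18), Enpep (-3.59), Slc44a5 (-3.22) and Cytip (-3.22) gave the largest losses. The Nr1h3 regions gave -0.40 (SE 0.21, limma adjusted p = 0.15) and -0.39 (SE 0.19, adjusted p = 0.13).

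Of the 148 shared regions of Kupffer identity genes, 42 were higher in Kupffer cells, 16 lower and 90 did not pass (42 and 19 adjusted over the list alone), while the list's mean change gave a permutation adjusted p of 0.083. Its group-only regions numbered 46 in Kupffer cells and 23 at 48 h against -27.3 net for matched lists (permutation adjusted p = 0.0063). Phagocytosis genes had 31 and 16 (0.0378), a call lost with regions assigned within 10 kb and with lists of equal length, while 20 of their 148 shared regions were higher, 22 lower and the rest did not pass (20 and 22 adjusted over the list alone). Timd4 and Marco belong to both lists. In all, 12178 of 46198 shared regions passed, 6337 higher and 5841 lower in Kupffer cells, relative to a shift of -0.28, and 2919 and 11666 without centring. The total was 6803 with all libraries in the fit, 8116 without Kupffer library 1, and 7945 and 6975 without 48 h libraries 1 and 2. Group-only peaks numbered 4568 in Kupffer cells and 12911 at 48 h, or 6987 and 6483 with lists of equal length, 5649 to 7710 and 15633 to 24421 without 1 library. Their sum of 17479 compares with 1964 in the highest of the other splits. At 48 h, where lists were longer, gene ends of other cells' markers also held more peaks than in Kupffer cells. The shares were 45.8% ± 5.89 against 25.0% for B cells (SD, n = 2) and 57.1% ± 10.1 against 39.3% ± 5.05 for T and NK cells. They were 66.7% against 45.8% ± 5.89 for dendritic cells and 18.75% against 9.38% ± 4.42 for hepatocytes. Neutrophil, stellate and endothelial markers went the same way.

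Kupffer cells and blood monocytes form the ends of the repopulation series. Itga9 had 21 regions in Kupffer cells alone and 2 in monocytes alone, Stab2, a scavenger receptor gene also used as an endothelial marker, had 15 and 0, and Marco had 11 and 0. Marco also rose at 3 of 4 shared regions, the strongest by 3.30 (SE 0.30, limma adjusted p = 5.0e-15), and Abca1 at 6 of 9, the strongest by 2.28 (SE 0.28, adjusted p = 1.6e-10). F13a1 had 7 regions in monocytes alone, Spn, a leukocyte sialophorin gene, had 5, and Ccr2, the receptor for monocyte recruitment, had 4 in monocytes and 1 in Kupffer cells. Smad3, a TGF-β signal transducer, had 7 regions in monocytes alone, and 7 of its 8 shared regions were lower in Kupffer cells. The region inside Enpp2, the autotaxin gene, held 388 ± 14.4 (SD, n = 2) in Kupffer cells and 10.0 ± 4.21 (n = 2) in monocytes, a log2 fold change of 5.59 (SE 0.25, limma adjusted p = 1.4e-29). Regions at Ubxn2b, Ccn1 and Abhd12 followed with 4.99, 4.94 and 4.89. The largest losses were at Dnajb12 (-4.25, SE 0.23, limma adjusted p = 1.3e-25), Gipc2 (-4.15) and Sptb (-3.90). Both Nr1h3 regions were higher in Kupffer cells, by 1.13 (SE 0.24, limma adjusted p = 7.7e-05) and 0.73 (SE 0.25, adjusted p = 0.012).

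Of the 72 shared Kupffer identity regions 34 were higher, 7 lower and 31 did not pass (35 and 7 adjusted over the list alone), with 125 regions in Kupffer cells alone and 15 in monocytes alone. Permutation adjusted p-values were 0.029 for the shared and 0.0021 for the group-only regions. Phagocytosis genes had 78 and 24 group-only regions (permutation adjusted p = 0.0137, lost within 10 kb), and of their shared regions 34 were higher, 15 lower and 52 did not pass (34 and 15 adjusted over the list alone). Of 37850 shared regions 19319 passed, 9741 higher and 9578 lower, relative to a shift of -0.39, and 3802 and 11825 without centring. The 12645 regions called in Kupffer cells alone are named Kupffer-gained regions here, and the 15624 called in monocytes alone form the monocyte set. Their sum of 28269 compares with 1115 in the highest of the other splits.

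Repopulating macrophages held 27.4% ± 6.85 (SD, n = 3) of the Kupffer-gained regions at 24 h and 56.9% ± 5.74 (n = 2) at 48 h. Every 48 h library lay above every 24 h library, and the exact permutation test (two-sided, the one-sided p doubled) gave p = 0.2, the smallest it can give for 3 against 2 libraries. Of the monocyte set they still held 58.1% ± 1.21 (n = 3) at 24 h and 58.5% ± 7.60 (n = 2) at 48 h (exact permutation p = 1). With lists of equal length the 48 h shares were 46.0% and 42.4%, while the 24 h shares moved by less than 1 SD between libraries. The like shares of the monocyte set at 24 and 48 h therefore hold only for the deposited lists, which were longer at 48 h. All 24 h libraries held 1727 of the Kupffer-gained regions, and Itga9 had 10 of these, the most of any gene. Both 48 h libraries held 6031 of them, and 4025, or 31.8%, were in no repopulating library, among them 14 at Timd4, and 16 at Dlgap2 and 15 at Tenm2, which were named after the values were seen. Those in no repopulating library also had a lower median signal in Kupffer cells, 17.65 against 33.3 for those in all 24 h libraries. A further 715 regions were called in all 24 h libraries but in no monocyte or Kupffer library, and 470 of these (65.7%) in both 48 h libraries. That count was 1344 without blood library 2, and 1176, 1150 and 1789 without 24 h libraries 1, 2 and 3.

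**Figure D2:**
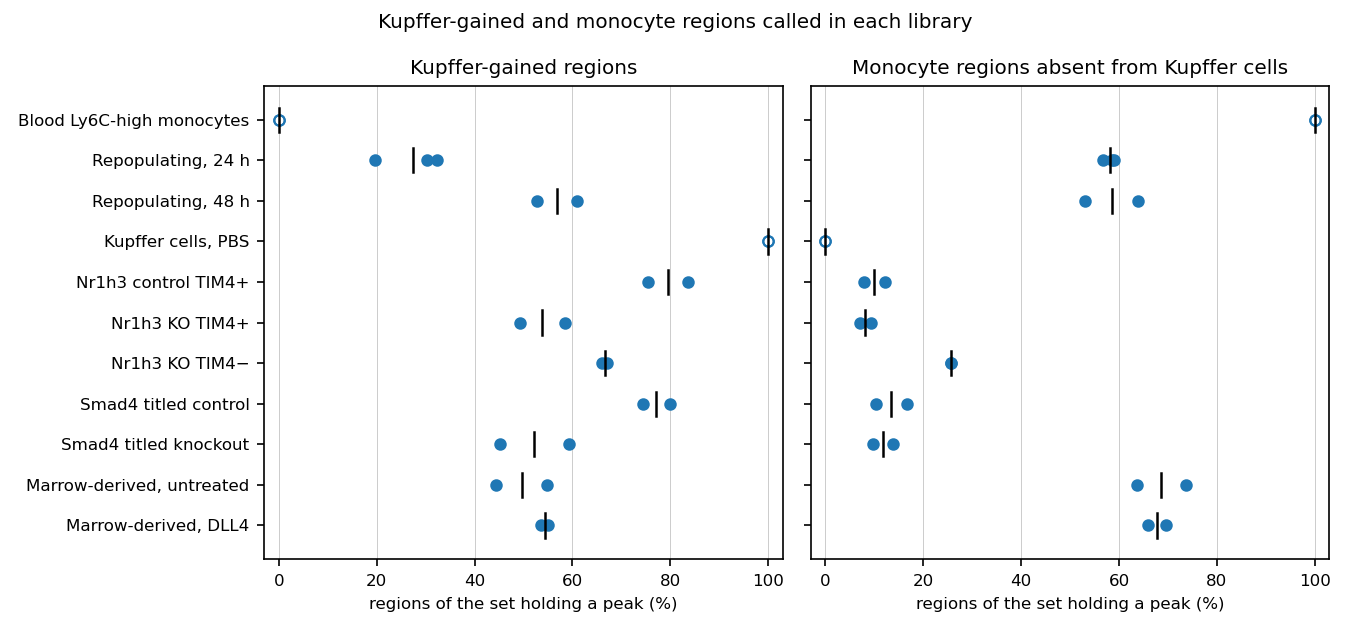
Percent of Kupffer-gained regions and of the monocyte set that hold a peak in each library, one point per library (open where the group defines the sets) with the mean of each group as a line. Kupffer-gained regions average 27.4% at 24 h and 56.9% at 48 h, while the monocyte set averages 58.1% and 58.5%, all with lists as deposited, which were longer at 48 h. With lists of equal length the 48 h averages of both sets were lower.

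The Nr1h3 experiment asked which accessible regions depend on LXRα in Kupffer cells. In TIM4+ knockout cells the LXR target Abca1 fell at 2 of 17 shared regions, the strongest by 2.39 (SE 0.21, limma adjusted p = 1.0e-25), and had 3 regions in the control alone. Scd1, the stearoyl-CoA desaturase gene, fell at 3 of 5, the strongest by 2.42 (SE 0.26, limma adjusted p = 6.4e-17). Cd5l fell at 3 of 5, the strongest by 1.67 (SE 0.22, limma adjusted p = 1.6e-11), and had 4 regions in the control alone. Of 134 shared regions of LXR targets 14 fell, 5 rose and 115 did not pass (16 and 9 adjusted over the list alone), and the list's mean change gave a permutation adjusted p of 0.12. Genes of inflammation rose, with 10 of 98 shared regions higher, 1 lower and 87 not passing (12 and 1 adjusted over the list alone, permutation adjusted p = 0.0084), such as Nlrp3, an inflammasome sensor gene, by 0.57 (SE 0.17, limma adjusted p = 0.015, and 0.060 after quantile normalisation). Of 170 shared Kupffer identity regions 10 rose, 11 fell and 149 did not pass (14 and 17 adjusted over the list alone, permutation adjusted p = 0.048, and 0.056 after quantile normalisation).

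The largest loss in TIM4+ knockout cells lay 6.03 kb from Plekhm1, a lysosome positioning gene (chromosome 11, 103418570 to 103418896), at 10.9 ± 1.93 (SD, n = 2) against 132 ± 44.3 (n = 2) in the control, a log2 fold change of -3.14 (SE 0.23, limma adjusted p = 1.8e-37). Ebf2 (-2.94), Ryr2 (-2.69) and Gtf2ird1 (-2.60) followed, and Txnrd1, the thioredoxin reductase gene, fell at 1 of 4 shared regions by 2.58. Gda (2.50, SE 0.29, limma adjusted p = 7.3e-15), Cytip (2.49), Taf1a (2.40), Osm, the oncostatin M gene (2.31), and Negr1 (2.30) gave the largest gains. Timd4 fell at 1 of 10 shared regions (-1.20, SE 0.28, limma adjusted p = 9.9e-04) and Clec4f at 1 of 7 (-0.71, SE 0.20, adjusted p = 0.0096). The Nr1h3 regions gave 0.35 (SE 0.16, limma adjusted p = 0.14) and 0.12 (SE 0.15, adjusted p = 0.69), and peaks there do not test whether the floxed sequence was deleted. Liver endothelial markers had 15 regions in the control alone against a mean of -3.42 net regions for matched lists (permutation adjusted p = 0.0084, lost with lists of equal length). Of these 15, 11 lie at Stab2, which is also on the phagocytosis list, and Pecam1, Tek, Emcn and Gata4, named after the values were seen, have 1 each. Of 22 shared regions of these markers 2 rose, 1 fell and 19 did not pass (3 and 1 adjusted over the list alone).

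In this comparison 3531 of 40231 shared regions passed, 1957 higher and 1574 lower, relative to a shift of -0.31. The split was 60 and 1405 without centring, 1121 and 1789 after quantile normalisation and 487 and 917 with all libraries of the experiment in the fit. The total was 1995 without knockout library 1, 1444 without control library 1 and 1280 without control library 2. The 612 Kupffer-gained regions that fell compare with 209 by chance (Fisher exact test, two-sided, odds ratio 4.57, adjusted p = 2.4e-149), where regions are not independent replicates and the use of shared regions was added after the data were seen. These regions were chosen for peaks in Kupffer cells, so part of their excess is built in. Their median log2 fold change was -0.084. Group-only peaks numbered 784 in TIM4+ knockouts and 5701 in controls, but 2034 and 2486 with lists of equal length. Without 1 library they were 1353 to 3183 and 7562 to 13082, and the sum of 6485 compares with 2416 in the highest of the other splits. Of the regions in TIM4+ knockouts alone, 136 belonged to the monocyte set against 15.8 by chance (Fisher exact test, odds ratio 11.5), or 253 against 26.3 with lists of equal length. Since the set lacks peaks in Kupffer cells by definition, part of an excess among regions absent from a Kupffer control is built in. The monocyte set was over-represented among regions in the control alone as well (odds ratio 2.12, Fisher adjusted p = 3.5e-19), but this did not pass with equal length (35 against 32.2, Fisher adjusted p = 0.61). TIM4+ knockouts held 53.9% ± 6.57 (SD, n = 2) of the Kupffer-gained regions and controls 79.5% ± 5.75 (n = 2). Lists of TIM4+ knockouts were shorter, with 51373.5 ± 3675 peaks against 62008 ± 5110 in controls (SD, n = 2). In both groups the library with the longer list held the larger share, and the shares were not computed with lists of equal length.

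In TIM4- knockout cells, compared with the same TIM4+ controls, Timd4 had 13 regions in the control alone, and TIM4 protein was the marker by which the groups were sorted. These groups differ in genotype and in TIM4, and there is no TIM4- control. Effects of the knockout and differences that go with TIM4 therefore cannot be told apart in this comparison. Marco fell at 10 of 11 shared regions, the strongest by 2.14 (SE 0.29, limma adjusted p = 5.5e-11). Of 180 shared Kupffer identity regions 38 fell, 10 rose and 132 did not pass (43 and 18 adjusted over the list alone, permutation adjusted p = 0.0042). Clec4f fell at 4 of 7 shared regions, from -0.75 (SE 0.16) to -1.74 (SE 0.32). LXR target regions fell at 22 of 137, rose at 7 and did not pass at 108 (28 and 7 adjusted over the list alone, permutation adjusted p = 0.038). Among them Abca1 fell at 5 of 18, the strongest by 3.71 (SE 0.24, limma adjusted p = 9.7e-41), and Cd5l at 4 of 5, the strongest by 2.09 (SE 0.22, adjusted p = 7.9e-18). Regions of inflammatory genes rose at 14 of 115 and fell at 4, with 97 not passing (15 and 4 adjusted over the list alone, permutation adjusted p = 0.0063), such as Traf1, a TNF receptor adaptor gene, by 1.47 (SE 0.32, adjusted p = 1.4e-04). Slc7a11 rose at 4 of 4 shared regions, the strongest by 1.85 (SE 0.28, limma adjusted p = 1.7e-08). Gene ends of dendritic cell markers held peaks at 62.5% ± 5.89 in TIM4- knockouts against 33.3% in controls (SD, n = 2). For B cells the shares were 37.5% ± 5.89 and 25.0% ± 11.8. Those of T and NK cells and hepatocytes were equal, endothelial and stellate ones slightly higher and neutrophil ones lower. Lists of TIM4- knockouts were longer.

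The largest gain lay 3.87 kb from Osm (chromosome 11, 4232717 to 4233116), at 126 ± 8.20 (SD, n = 2) against 6.81 ± 0.636 (n = 2), a log2 fold change of 3.62 (SE 0.26, limma adjusted p = 1.3e-33). Cytip (2.92), Negr1 (2.62), Plec (2.49) and Runx2 (2.48) followed. The largest losses with a gene within 50 kb were at Marchf4 (-4.10), the mineralocorticoid receptor gene Nr3c2 (-3.81, SE 0.19, limma adjusted p = 4.9e-59), Bmp2k (-3.77) and Nova1 (-3.77). The Nr1h3 regions gave 0.17 (SE 0.16, limma adjusted p = 0.51) and 0.27 (SE 0.15, adjusted p = 0.24). Phagocytosis genes without Timd4, the gene of the sorting marker, had 13 regions in TIM4- knockouts alone and 18 in controls alone (permutation adjusted p = 0.28, a test added after the data were seen), 11 of the latter at Stab2. The planned test, which includes the 13 control regions of Timd4, gave a permutation adjusted p of 0.0084, while 15 of their 163 shared regions rose, 16 fell and 132 did not pass (15 and 17 adjusted over the list alone). Liver endothelial markers had 13 regions in controls alone (permutation adjusted p = 0.0154), 11 of them at Stab2, and of 28 shared regions 3 rose, 4 fell and 21 did not pass (4 and 4 adjusted over the list alone).

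Of 46888 shared regions 6430 passed, 3296 higher and 3134 lower, relative to a shift of 0.40. The split was 12329 and 1178 without centring, 1701 and 2577 after quantile normalisation and 857 and 2038 with all libraries in the fit. The total was 3802 without knockout library 1 and 3268 without control library 2. Kupffer-gained regions fell 1403 times against 438 by chance (Fisher exact test, odds ratio 6.07), an excess that is partly built in by their choice for peaks in Kupffer cells. Group-only peaks numbered 5578 in TIM4- knockouts and 2957 in controls, but 3246 and 3730 with lists of equal length. Without 1 library they were 7242 to 10852 and 4274 to 6900, and the sum of 8535 compares with 2051 in the highest of the other splits. Of the regions in TIM4- knockouts alone, 1426 belonged to the monocyte set against 255 by chance (Fisher exact test, odds ratio 12.8), or 740 against 99.2 with lists of equal length. Here too part of the excess is built in, since both the set and these regions lack peaks in Kupffer cells. Among shared regions that rose, where part of an excess is built in as well, the set had 53 against 43.0 (odds ratio 1.26, Fisher adjusted p = 0.12), and 58 against 22.2 after quantile normalisation (odds ratio 2.85). TIM4- knockouts held 66.6% ± 0.665 (SD, n = 2) of the Kupffer-gained regions and 25.7% ± 0.0543 (n = 2) of the monocyte set, of which controls held 10.0% ± 3.15 (n = 2). Lists of TIM4- knockouts were longer, with 68685 ± 102 peaks against 62008 ± 5110 in controls (SD, n = 2), and these shares were not computed with lists of equal length.

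The direct comparison of TIM4- with TIM4+ knockout cells shows how these cell populations differ. Both knockout results share their control libraries, which are TIM4+, so the effect of the knockout was not compared between TIM4- and TIM4+ cells. Timd4 had 9 regions in TIM4+ cells alone. Of 163 shared regions of Kupffer identity genes 10 were lower in TIM4- cells and 153 did not pass (16 lower adjusted over the list alone), with a permutation adjusted p of 0.11. Of these 10, 7 lay at Marco, named here after the values were seen, 2 at C6 and 1 at Clec4f. Slc7a11 was higher in TIM4- cells at 4 of 5 shared regions, the strongest by 1.83 (SE 0.29, limma adjusted p = 1.4e-06). Ly6c2, the Ly6C antigen gene of monocytes, was lower at 3 of 3, the strongest at -1.76 (SE 0.23, limma adjusted p = 1.2e-09), but had 2 regions in TIM4- cells alone. The versican gene Vcan, named after the values were seen, was higher at 1 of 2 (1.08, SE 0.18, limma adjusted p = 5.9e-06). Monocyte genes had 16 regions in TIM4- cells alone (permutation adjusted p = 0.765), and 1 of 59 shared regions was higher, 3 lower and 55 did not pass (1 and 4 adjusted over the list alone). The complement gene C6 was lower at 2 of 4, the strongest at -1.79 (SE 0.33, limma adjusted p = 4.5e-05). Amot (1.99, SE 0.24, limma adjusted p = 4.3e-11), Pxylp1 (1.88), Mef2c (1.76) and Lrrk2 (1.74) gained most, and Ccdc149 (-3.06, SE 0.30, adjusted p = 8.5e-16), Ccn1 (-2.53), Nova1 (-2.50) and Cntnap2 (-2.48) lost most. Clec4f was lower at 1 of 7 (-1.19, SE 0.33, limma adjusted p = 0.026, and 0.23 after quantile normalisation).

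In all, 881 of 41838 shared regions passed, 254 higher and 627 lower in TIM4- cells, relative to a shift of 0.75. The split was 28314 and 147 without centring, 139 and 314 after quantile normalisation, 180 and 292 without the weakest regions and 54 and 373 with all libraries in the fit. The total was 399 and 417 without TIM4- libraries 1 and 2, and 453 without TIM4+ library 1. Of the regions lower in TIM4- cells, 307 were Kupffer-gained against 77.4 by chance (Fisher exact test, odds ratio 7.18, adjusted p = 1.2e-112). Of the regions in TIM4- cells alone, 1497 belonged to the monocyte set against 408 by chance (odds ratio 7.69), or 231 against 36.5 with lists of equal length (odds ratio 9.04). Part of this excess is built in, since the set is defined by the absence of peaks in Kupffer cells. Regions in TIM4+ cells alone held 16 against 21.0, but 89 against 32.5 with equal length (odds ratio 3.03). Group-only peaks numbered 8563 in TIM4- and 441 in TIM4+ cells, but 1757 and 1567 with lists of equal length. Without 1 library they were 11180 to 14949 and 915 to 2045, and the sum of 9004 compares with 1656 in the highest of the other splits. T and NK cell markers had 16 regions in TIM4- cells alone and 1 in TIM4+ cells alone (permutation adjusted p = 0.0042), but the net count turned to -3 with lists of equal length. Peaks at the ends of these marker genes were at 42.9% of them in TIM4- cells and in controls and at 21.4% ± 10.1 (SD, n = 2) in TIM4+ knockout cells.

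**Figure D3:**
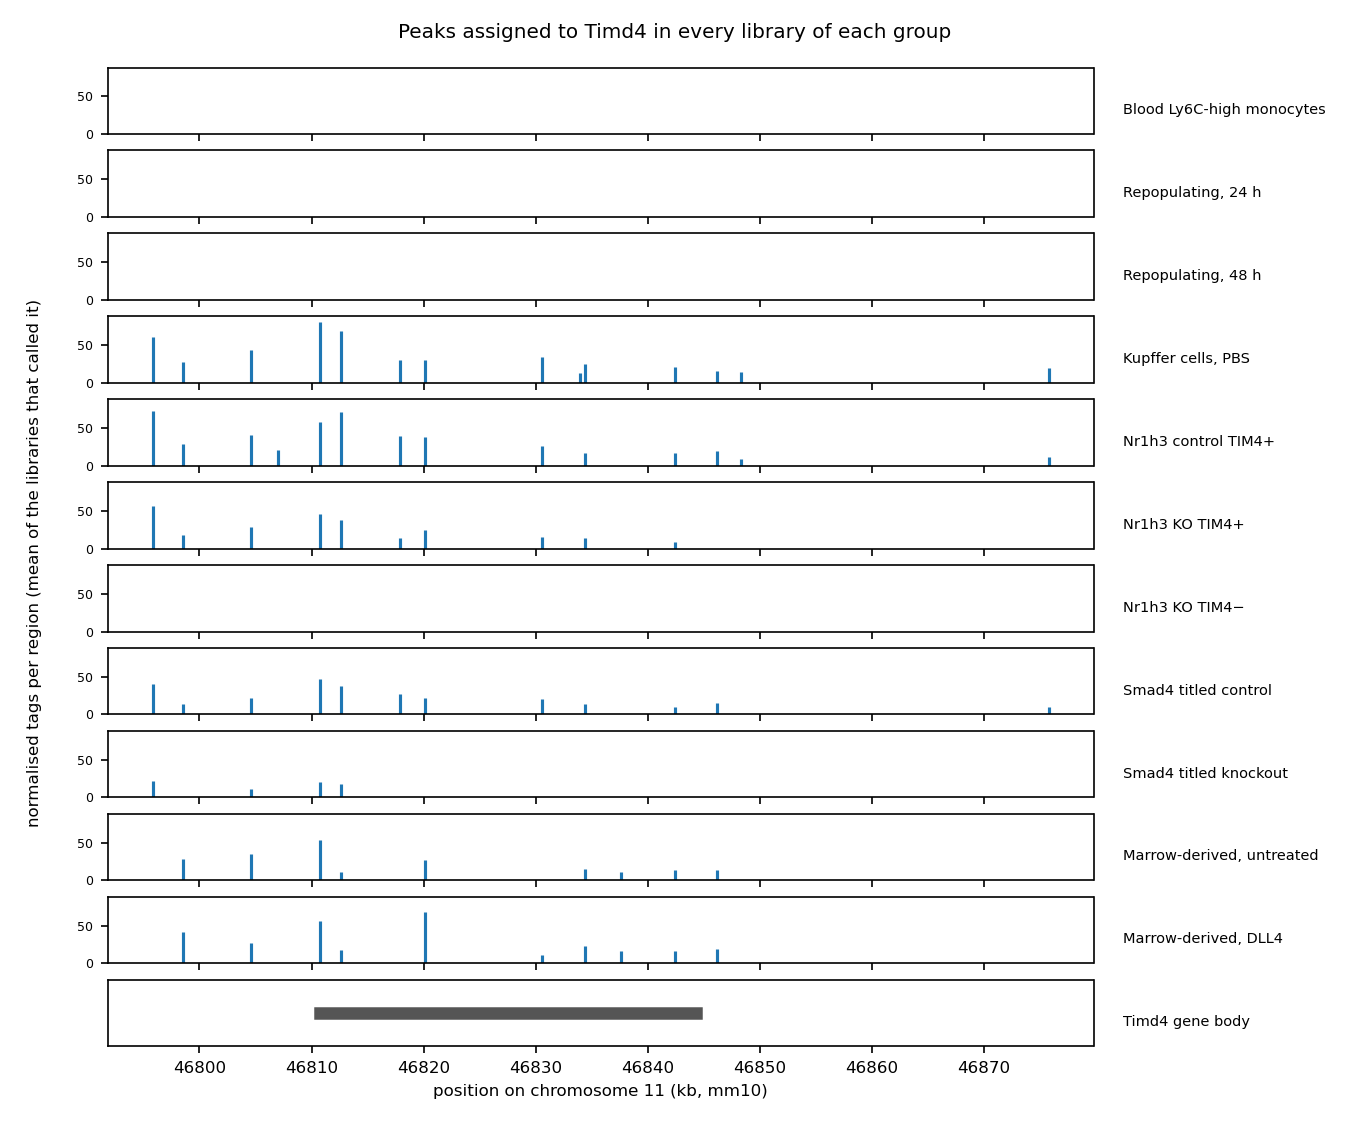
Regions at Timd4 called in every library of each group, by position on chromosome 11 (kb, mm10), with bar height the mean normalised tag count and the gene body drawn below. Kupffer cells and Nr1h3 controls have 14 such regions and TIM4+ knockouts 10, while the panels of monocytes, repopulating macrophages and TIM4- knockouts are empty.

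The Smad4 experiment addressed the signal transducer of TGF-β and BMP receptors. In the libraries titled knockout, Kupffer identity genes lost accessibility, a direction that rests on the titles. Peaks at the gene ends of other cells' markers were also fewer there than in those titled control for B cells (16.7% against 29.2% ± 5.89, SD, n = 2), T and NK cells (32.1% ± 5.05 against 42.9%), neutrophils (8.33% against 16.7%), stellate cells (25.0% against 33.3%) and liver endothelium (15.6% ± 4.42 against 21.9% ± 4.42). They were equal for dendritic cells (41.7%) and more for hepatocytes (15.6% ± 4.42 against 12.5%). Lists of the libraries titled knockout were shorter, with 53420.5 ± 5632 peaks against 64141 ± 4828 in those titled control (SD, n = 2). Neither these shares nor the regions of single genes in the libraries titled control alone were computed with lists of equal length. Of the 149 shared regions of Kupffer identity genes 10 fell and 139 did not pass (13 lower adjusted over the list alone). The mean change of the Kupffer identity list was -0.24 against 0.05 ± 0.05 (SD) for matched lists (permutation adjusted p = 0.0021). Clec4f had 4 regions in the libraries titled control alone, and its shared region fell by 1.23 (SE 0.20, limma adjusted p = 5.0e-06), from 83.75 ± 11.4 (SD, n = 2) to 27.8 ± 5.37 (n = 2). Marco had 3 such regions and fell at 1 of 7 shared ones (-0.89, SE 0.22, limma adjusted p = 0.0065), and Timd4 fell at 1 of 4 (-0.85, SE 0.24, adjusted p = 0.027, and 0.071 after quantile normalisation). Abca1 had 4 regions in the libraries titled control alone and fell at 2 of 17 shared ones, the strongest by 1.22 (SE 0.17, limma adjusted p = 1.6e-07). Cx3cr1, the fractalkine receptor gene, rose at 3 of 7, the strongest by 1.56 (SE 0.31, limma adjusted p = 4.0e-04), and had 1 region in the libraries titled control alone. Of 62 shared regions of monocyte genes 5 rose, 2 fell and 55 did not pass (7 and 6 adjusted over the list alone, permutation adjusted p = 0.54), and 1 region was in the libraries titled knockout alone and 10 in those titled control alone. Osm (2.80, SE 0.29, limma adjusted p = 1.0e-11), Slco2b1 (2.53), Runx3 (2.40), Nup188 (2.26) and Runx2 (2.17) gained most. Ebf2 (-2.43, SE 0.21, limma adjusted p = 4.3e-15) and H13 (-2.37) gave the largest losses with a gene within 50 kb.

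Among TGF-β and BMP target genes 5 of 124 shared regions rose, 6 fell and 113 did not pass (9 and 8 adjusted over the list alone). Tgfbi, a TGF-β-induced matrix gene, rose at 1 of 6 shared regions by 1.22 (SE 0.32, limma adjusted p = 0.013, and 0.057 after quantile normalisation), and Tgfbr2, a TGF-β receptor gene, had 5 regions in the libraries titled control alone. The Smad4 regions gave -0.19 (SE 0.26, limma adjusted p = 0.80) and 0.12 (SE 0.18, adjusted p = 0.83), which does not tell which libraries carry the deletion. Of 40067 shared regions 1232 passed, 629 higher and 603 lower in the libraries titled knockout, relative to a shift of -0.34. The split was 28 and 502 without centring, 253 and 414 after quantile normalisation and 388 and 635 without the weakest regions. The total was 796 without library 1 titled knockout, and 524 and 336 without libraries 1 and 2 titled control. Kupffer-gained regions fell 291 times against 72.5 by chance (Fisher exact test, odds ratio 7.20, adjusted p = 7.4e-108), and regions of the monocyte set rose 31 times against 6.81 (odds ratio 5.02, adjusted p = 5.7e-12). Part of each excess is built in, since Kupffer cells of PBS mice have peaks in the former set and none in the latter by definition. The median log2 fold change of the Kupffer-gained regions was -0.079. Group-only peaks numbered 978 in libraries titled knockout and 5523 in those titled control, but 2160 and 2424 with lists of equal length. Without 1 library they were 1716 to 4477 and 7250 to 13636, and the sum of 6501 compares with 2892 in the highest of the other splits. Of the regions in libraries titled knockout alone, 213 belonged to the monocyte set against 27.6 by chance (Fisher exact test, odds ratio 10.9), or 344 against 41.8 with lists of equal length. As for Nr1h3, part of this excess is built in by the definition of the set. Regions in libraries titled control alone held 289 against 156 (odds ratio 2.10), or 69 against 46.9 with equal length (odds ratio 1.52).

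**Figure D4:**
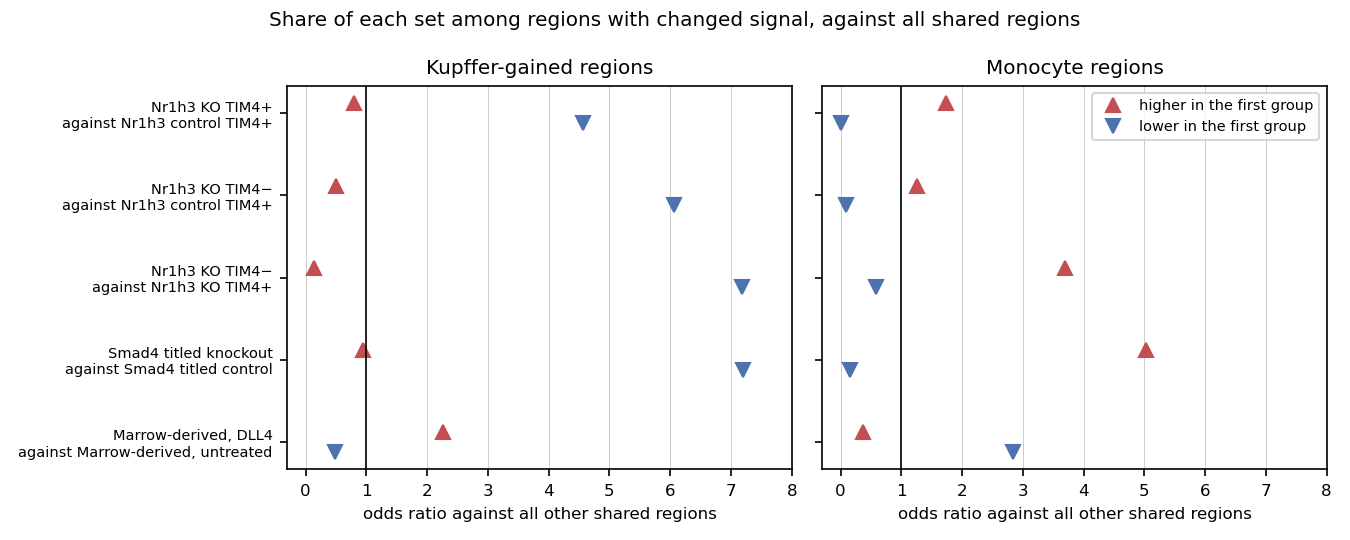
Odds ratio (linear axis) of Kupffer-gained regions and of the monocyte set among shared regions that were higher or lower in each comparison, with a line at 1. Kupffer-gained regions are over-represented among regions lower in TIM4+ (4.57) and TIM4- (6.07) Nr1h3 knockouts and in the libraries titled Smad4 knockout (7.20), and among regions higher with DLL4 (2.26). Against Kupffer controls part of an excess of either set is built in by how the sets were defined.

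The culture experiment asked what Notch ligand does to macrophages grown without a liver. Hes1, the classical Notch target, rose with DLL4 at 4 of 6 shared regions, while a region inside the gene was called in both untreated libraries (29.25 ± 2.90, SD, n = 2) and in no DLL4 library, and another 28.7 kb away with DLL4 alone. The strongest, 0.164 kb from the gene (chromosome 16, 30065071 to 30065315), went from 29.6 ± 2.76 (SD, n = 2) to 171 ± 2.26 (n = 2), a log2 fold change of 2.46 (SE 0.18, limma adjusted p = 6.0e-26), followed by 2.25, 1.98 and 0.64 at the others, the last of which no longer passed after quantile normalisation (adjusted p = 0.13). Of 95 shared regions of Notch targets 9 rose and 86 did not pass (13 higher and 4 lower adjusted over the list alone, permutation adjusted p = 0.0073). Hey1 gave 0.56 (SE 0.24, limma adjusted p = 0.19) and 0.17 (SE 0.18, adjusted p = 0.69), Nrarp 0.98 (SE 0.35, adjusted p = 0.087) and 0.13 (SE 0.16, adjusted p = 0.73), and Dtx1 -0.10 (SE 0.32, adjusted p = 0.92). Kupffer identity genes rose at 19 of 175 shared regions, fell at 3 and did not pass at 153 (25 and 3 adjusted over the list alone, permutation adjusted p = 0.0021). Of these 19, 11 lay at Itga9, which rose at 11 of 24, the strongest by 1.73 (SE 0.32, limma adjusted p = 6.8e-05). The count thus rests largely on Itga9, while the permutation test takes the mean over genes, and neither was repeated without it. Timd4 rose at 1 of 9, by 1.27 (SE 0.23, limma adjusted p = 4.8e-05). Spic, a transcription factor gene of iron-recycling macrophages that stands on several of the lists, rose at 2 of 3, the strongest by 1.16 (SE 0.34, limma adjusted p = 0.030, and 0.055 after quantile normalisation). Clec4f moved the other way at 1 of 3 (-0.65, SE 0.19, limma adjusted p = 0.031), and one of the pair of Nr1h3 regions rose by 0.72 (SE 0.23, adjusted p = 0.049). Both missed the limma threshold after quantile normalisation (adjusted p = 0.066 and 0.13).

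Zfp366 (2.20, SE 0.30, limma adjusted p = 1.5e-08) and Runx3 (2.16) were the next largest gains with a gene within 50 kb, and Cltc (-1.86, SE 0.29, adjusted p = 1.9e-06), Elovl7 (-1.78), Cd93 (-1.70) and Srp9 (-1.65) the largest losses. Of 86 shared regions of iron and heme genes 83 did not pass and 3 were higher (3 adjusted over the list alone, permutation adjusted p of the mean change 0.047), 2 of them at Spic and 1 at Slc40a1, the iron exporter ferroportin, by 0.60 (SE 0.17, limma adjusted p = 0.026, and 0.076 after quantile normalisation). In all, 2793 of 72015 shared regions passed, 1700 higher and 1093 lower, with a median shift of 0.03. The split was 1912 and 636 without centring and 634 and 515 after quantile normalisation. The total was 843 and 1109 without DLL4 libraries 1 and 2, and 145 and 1270 without untreated libraries 1 and 2. Kupffer-gained regions rose 239 times against 118 by chance (Fisher exact test, odds ratio 2.26, adjusted p = 4.0e-25), and regions of the monocyte set fell 289 times against 125 (odds ratio 2.85, adjusted p = 1.1e-42). Group-only peaks numbered 2500 with DLL4 and 2377 without, against a sum of 4670 in the highest of the other splits, so 4877 was close to what mixed groups gave. Of the 50 strongest in each group, 40 and 34 had a peak of the other group within 1 kb, and of all of them 30.0% and 31.8%. Without 1 library the counts were 3591 to 9657 and 4603 to 11675.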

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

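The comparison of these counts was fixed before the data were examined, and the tests of list length and of admixture quoted in this closing section were chosen after the results were seen. TIM4- and TIM4+ Nr1h3 knockout cells differed at 881 shared regions (limma), 627 lower and 254 higher in TIM4- cells relative to a median shift of 0.75. Without centring 147 were lower and 28314 higher, so the direction holds only relative to that shift. The TIM4- cells have no control of their own kind here, so a difference between TIM4- and TIM4+ cells that does not need the knockout was not separated from one that does.

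Of the group-only regions of the TIM4+ Nr1h3 comparison 87.9% belonged to the control, and 55.0% with lists of equal length. For the Smad4 comparison the share of the libraries titled control was 85.0%, and 52.9% with lists of equal length. A share of 40% to 60% was first taken as support for list length as the cause. That reading was dropped after the values were seen, since equal length draws the counts of both groups together by construction and gave 43.0% to 55.0% in all 9 comparisons. The origin of the asymmetry stays open.

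Kupffer-gained regions fell more often than others in TIM4+ Nr1h3 knockouts (11.5% of them) and in the libraries titled Smad4 knockout (6.04%). Their median log2 fold changes were -0.084 and -0.079. They were chosen for peaks in Kupffer cells, so part of the excess is built in. Against other regions of matched signal the ratio was 3.57 (11.5% against 3.22%) and 6.42 (6.04% against 0.941%), which argues against a bias with signal strength. Matching on signal does not remove the built-in part. Of the Kupffer-gained regions 6.90% and 4.22% lay below a log2 fold change of -1, against at most 0.0750% and 0.0831% in splits that mix the groups. This was first read against an admixture of cells that lack the regions. That reading was dropped after the values were seen, since other regions passed the same bound (1.00% against 0.0459% and 0.411% against 0.0397%). Regions lost altogether are not among those tested. Whether the losses start at these regions, follow from a change of cell state or come from admixed cells stays open. For Smad4 the direction rests on the titles.

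Fold changes of the TIM4+ Nr1h3 and the titled Smad4 comparisons ran together over 34631 regions (Pearson r = 0.380, at most 0.0904 in splits that mix the groups), which are not independent replicates. Had a lower share of tags in peaks in both knockout groups made this, r would be below 0 for TIM4- knockouts. Their share is above that of their controls, and they gave r = 0.384 with Smad4 (at most 0.0558). They also differ from these controls in TIM4 and share them with the TIM4+ comparison. The value therefore does not exclude such a bias in the TIM4+ correlation. Outside the Kupffer-gained regions and the monocyte set the TIM4+ and Smad4 comparisons gave r = 0.319 (at most 0.0912), so these sets alone do not make the correlation. A candidate explanation is a shared shift toward the state at 48 h of repopulation, since Kupffer cells against 48 h gave r = -0.346 with the Smad4 comparison and -0.385 with the TIM4+ comparison (at most 0.0464 and 0.102). Kupffer cells against 24 h or blood were not tried, so such a shift is not told apart from another loss of Kupffer cell signal. With the strain labels in place of the titles every sign that involves Smad4 would turn, and the question stays open until the genotypes are known.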

How the results depend on the processing

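The list signal test, the lists without Timd4, the overlap with shared regions and the setting of equal length without regions of the full lists were chosen only after results were seen, and the other settings before the data were examined. The cause of the movements was not tested except where the construction of a setting shows it. A count is called moved when it lies more than 1.5 times above or below the main count, whatever its split into higher and lower, and a share when it moved by 1 SD between libraries or more. Reversed and weakened are used of odds ratios and list tests, by direction and adjusted p. Models of counts with DESeq2 or edgeR were not run, since the deposited values are scaled tags of called peaks only, and motif tests were not run, since no genome sequence was used here.

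Lists of equal length lower the longer list and raise the shorter one by construction. Group-only regions became 2256 at 48 h and 1702 at 24 h, 6987 in Kupffer cells and 6483 at 48 h, 2034 in TIM4+ Nr1h3 knockouts and 2486 in controls, and 3246 in TIM4- knockouts against controls. They became 1757 in TIM4- and 1567 in TIM4+ knockouts, and 2160 in the libraries titled Smad4 knockout and 2424 in those titled control. The 48 h shares became 46.0% of Kupffer-gained regions and 42.4% of the monocyte set. Reversed were the net count of T and NK markers between TIM4- and TIM4+ knockouts, at -3, and the odds ratio of Kupffer-gained regions among regions in TIM4- knockouts alone, against TIM4+ ones, at 1.01 from 0.818. At 1.01 (Fisher adjusted p = 0.89) the depletion was lost without an opposite result. Odds ratios of the monocyte set were not among the counted alternatives, and that among regions in TIM4+ knockouts alone, against TIM4- ones, went from 0.751 (Fisher adjusted p = 0.328) to 3.03 (Fisher adjusted p = 3.0e-17). The larger of the counts changed sides for TIM4- knockouts against controls, to 3246 and 3730, and for Kupffer cells against 48 h, to 6987 and 6483, and against blood, to 13583 and 13067. By the rules given above, 13 of 46 alternatives moved, 2 reversed, 3 weakened and 28 kept their label.

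With equal length and the full lists of the other group removed, which can only lower the counts, they were 1797 at 48 h against 24 h, 6070 at 48 h against Kupffer cells, 2089 in Nr1h3 controls against TIM4+ knockouts, 2505 in TIM4- knockouts against controls, 1414 in TIM4- against TIM4+ knockouts, 1802 in the libraries titled Smad4 control, 1300 with DLL4 and 1425 untreated. With the stricter tag threshold they were 3327 at 48 h against 24 h, 7880 at 48 h against Kupffer cells, 414 in TIM4+ knockouts and 3189 in their controls, and 2720 in TIM4- knockouts against controls. They were also 3846 in TIM4- against TIM4+ and 277 in TIM4+ against TIM4- knockouts, 553 in the libraries titled Smad4 knockout and 2797 in those titled control, 1221 with DLL4 and 1264 untreated. Widened and trimmed peaks moved none of 18 and 23 alternatives past these bounds.

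Without centring limma called 1357 regions for 48 h against 24 h, 1465 for TIM4+ and 13507 for TIM4- knockouts against controls, 28461 for TIM4- against TIM4+ and 530 for Smad4, where the general shift between libraries counts as signal by construction and the larger direction turned in 7 of 9 comparisons. Quantile normalisation gave 1449 for 48 h against 24 h, 4278 for TIM4- knockouts against controls, 453 for TIM4- against TIM4+, 667 for Smad4 and 1149 for DLL4. It turned the larger direction for 48 h against 24 h (845 higher, 604 lower), Kupffer cells against blood (9229 and 9836), TIM4+ (1121 and 1789) and TIM4- knockouts against controls (1701 and 2577) and Smad4 (253 and 414). All libraries of the experiment in the fit kept the tested regions, took the variance from all groups and left out the mean-variance trend, so it changes more than 1 step, and gave 806 for 48 h against 24 h, 6803 for Kupffer cells against 48 h, 1404 for TIM4+ and 2895 for TIM4- knockouts against controls and 427 for TIM4- against TIM4+. It turned the larger direction for 48 h against 24 h (414 and 392), TIM4+ (487 and 917) and TIM4- knockouts against controls (857 and 2038). Leaving out the weakest regions gave 472 for TIM4- against TIM4+, and the other 8 counts stayed within 1.5 times. Its split turned to 1874 higher and 2425 lower for TIM4- knockouts against controls, 388 and 635 for Smad4 and 7760 and 8605 for Kupffer cells against blood. A pseudocount of 5 kept all 9 counts within 1.5 times, the largest change being 1198 calls for TIM4- against TIM4+.

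Regions assigned within 10 kb kept the label of 10 of 13 list results and weakened 3, and within 100 kb all 13 kept it. Of the list tests on group-only regions 12 passed as planned, 9 within 10 kb, 12 within 100 kb and 11 with lists of equal length. For TIM4- knockouts against controls 2 of these calls were lost without Timd4, the gene of the sorting marker. The net count of phagocytosis genes went from -18 to -5 (permutation adjusted p = 0.28) and that of Kupffer identity genes from -23 to -10 (permutation adjusted p = 0.075). The replicate numbers of the titles are shared between groups only as numbers, and the correlations of deviations between libraries of the same number were 0.00884, -0.00429, 0.0611 and -0.0380. With them as a replicate block limma called 4305 regions for TIM4+ and 6547 for TIM4- knockouts against controls, 1127 for TIM4- against TIM4+ and 2371 for DLL4.

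Leaving out 1 library moved 85 of 159 alternatives. Group-only counts can only rise, since fewer libraries must hold or lack a peak. They ran from 3635 to 5562 at 24 h and 5505 to 9159 in blood, 6318 to 13871 at 48 h and 1088 to 2358 at 24 h, and 5649 to 7710 in Kupffer cells and 15633 to 24421 at 48 h. They ran from 1353 to 3183 in TIM4+ knockouts and 7562 to 13082 in controls, 7242 to 10852 in TIM4- knockouts and 4274 to 6900 in controls, and 11180 to 14949 in TIM4- and 915 to 2045 in TIM4+ knockouts. They ran from 1716 to 4477 in the libraries titled Smad4 knockout and 7250 to 13636 in those titled control, and 3591 to 9657 with DLL4 and 4603 to 11675 untreated.

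Calls by limma with 1 library left out ran from 5386 to 15131 for 24 h against blood, 171 to 4992 for 48 h against 24 h, 6975 to 12199 for Kupffer cells against 48 h, 1280 to 3923 for TIM4+ and 3268 to 4923 for TIM4- knockouts against controls, 399 to 959 for TIM4- against TIM4+, 336 to 998 for Smad4 and 145 to 1270 for DLL4. The larger direction turned to lower without TIM4+ knockout library 1 (741 higher, 1254 lower), without any library of TIM4- knockouts against controls (from 2436 and 2487 to 1617 and 2185), without library 1 or 2 titled Smad4 knockout (265 and 531, 380 and 618) or library 2 titled control (163 and 173), and without DLL4 library 2 (550 and 559). For Kupffer cells against blood it turned without either Kupffer library (8772 and 8977, 9189 and 9246). The share of Kupffer-gained regions ran from 23.8% to 34.8% at 24 h and 49.9% to 62.4% at 48 h, that of the monocyte set from 47.0% to 63.1% and 49.3% to 64.2%, and the count of transient regions from 715 to 1789.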

Other observations

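The recurrences named here were picked after the values were seen, and no test was made for them beyond those of the single comparisons. TIM4+ and TIM4- Nr1h3 knockouts were compared with the same control libraries, so a like change in both is partly built in and is no independent recurrence. The Smad4 directions rest on the titles and would turn with the strain labels. The region 3.87 kb from Osm rose in 3 comparisons, by 3.62 (SE 0.26) in TIM4- and 2.31 (SE 0.31) in TIM4+ Nr1h3 knockouts and by 2.80 (SE 0.29) in the libraries titled Smad4 knockout. Oncostatin M is a cytokine of the interleukin 6 family that acts on hepatocytes and stromal cells. The region inside Runx2, a transcription factor gene, rose in TIM4- Nr1h3 knockouts (2.48, SE 0.25) and in the libraries titled Smad4 knockout (2.17, SE 0.28). The region inside Ebf2, a transcription factor gene of brown fat, fell in TIM4+ Nr1h3 knockouts (-2.94, SE 0.21) and in the libraries titled Smad4 knockout (-2.43, SE 0.21). The region inside Cytip, which encodes a binding partner of cytohesin, was lower in Kupffer cells than at 48 h (-3.22, SE 0.29) and higher in TIM4+ (2.49, SE 0.28) and TIM4- (2.92, SE 0.25) knockouts. The region beside Ubxn2b rose from 24 to 48 h by 2.98 (SE 0.30), and from monocytes to Kupffer cells by 4.99 (SE 0.25).

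The shares of both sets overlapped between DLL4-treated and untreated cultures. Untreated macrophages held 49.6% ± 7.28 (SD, n = 2) of the Kupffer-gained regions and DLL4-treated ones 54.3% ± 1.05 (n = 2), while 68.7% ± 7.02 (n = 2) and 67.7% ± 2.60 (n = 2) of the monocyte set were called. Untreated library 1, at 54.7% of the Kupffer-gained regions, lay above DLL4 library 2, at 53.6%. Timd4 had 9 regions called in every untreated library and 10 in every treated one, so its accessibility in culture did not need DLL4.

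Dendritic cell markers had peaks at the gene ends of 62.5% ± 5.89 (SD, n = 2) of genes in blood monocytes, 58.3% ± 8.33 (n = 3) and 66.7% (n = 2) in repopulating macrophages at 24 and 48 h, and 45.8% ± 5.89 (n = 2) in Kupffer cells. The share was 75.0% (n = 2) in untreated and 79.2% ± 5.89 (n = 2) in DLL4-treated cultured macrophages. It was 62.5% ± 5.89 (n = 2) in TIM4- Nr1h3 knockouts, 33.3% (n = 2) in controls and 29.2% ± 5.89 (n = 2) in TIM4+ knockouts. Peak lists of TIM4- knockouts were longer than those of both other Nr1h3 groups, so these shares do not tell which cells the libraries held.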
